A study of Homo sapiens with 2 samples.

How the data were processed

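The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions, the annotation release and the genome build are not given in the sources used here. Per the labels' protocols, total RNA was purified with a column kit and DNase, and biotinylated cDNA was made from it with the WT PLUS kit. RMA as a method combines the probes of a set into 1 log2 value after background correction and normalization between arrays, so the values are relative signals, and fold changes on such arrays are commonly compressed. The columns had quartiles of 2.33 and 5.01 on the control array and 2.34 and 5.01 on the array labelled knockdown, with medians of 3.16 and 3.17 and values from 0.803 to 13.2, so they were used as deposited. Exactly equal values on both arrays occurred in 1041 genes above the floor (6.63%), and these count as neither higher nor lower. Scanner files were not used here, and depth does not apply to arrays: their number, 1 per group, limits the precision.

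Groups were taken from the genotype label, and no label used here says how many cultures of each derivative were grown. Of the 70523 probe sets, 23781 named 1 gene in the platform annotation, 1543 named several and 45199 were unnamed here. Probe sets of several genes and unnamed ones were left out, and of several probe sets of a gene (479 genes) the one with the highest mean stood for it. Among the genes, 636 had the same values on both arrays as another gene, as genes with shared probes would. Symbols and gene types were updated through an NCBI RefSeq gene table (GRCh38.p14), which gave a type to 15522 of 15702 genes above the floor. The build of the array's clusters is not stated, so no coordinates are given. The expression floor, 3.21 log2 units, was the 95th percentile of the mean signal of 364 olfactory receptor genes, and a gene was kept when the higher of its values was above it. By the same criterion 27 of those 364 genes passed.

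The comparison was the log2 signal of the array labelled knockdown minus that of the control array. No test was possible with 1 array per group. Genes were counted at 2-fold, and 34 gene lists of pathways, cell states and other cell types, 1097 memberships in all, were described by their members beyond 1.5-fold and by the percentile of their median among 10000 random lists of the same size, matched on mean signal in 20 bins. Of the memberships, 851 were above the floor, 120 below it, 68 on probe sets of several genes and 58 were not analysed here, having no probe set named for them in the annotation used. The gene lists, the floor, the thresholds and the rule for named genes were fixed before the data were examined. That rule named SREBF1, a fixed panel of lipid and mesenchymal genes, the 12 highest and 12 lowest protein-coding genes, and up to 2 members per list and direction beyond 1.5-fold. The 12 highest and lowest left out non-coding RNAs, pseudogenes, uncharacterised loci, replication-dependent histones, olfactory receptors and immune receptor segments. Genes named outside the rule are marked as such.

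The alternatives subtracted the median difference or a loess curve of the difference on the mean signal (fraction 0.3), averaged probe sets of a gene, dropped or raised the floor or set it on the mean of the arrays, used thresholds of 1.5-fold and 3-fold, kept only protein-coding genes, added probe sets of several genes, and used list means or unmatched random lists. List members found in no other list, and counts with values under the floor set to the floor, were examined as alternatives chosen after seeing the data. The code was tested on simulated data, in which differences were drawn from a normal distribution with the SD of genes of the same level, 50 genes were set apart at each fold size and lists of 22 genes, the number measured in the fatty acid list, and of 30 genes were shifted by fixed amounts. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.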

Results

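Gene expression was measured in MDA-MB-231 cells, an established human line of triple-negative breast cancer with mesenchymal features. The series compared 2 stable derivatives of this line: control cells carrying the pLKO.1 vector and cells carrying a short hairpin RNA against SREBP1. SREBP1, encoded by SREBF1, is a transcription factor that drives genes of fatty acid synthesis. Each derivative was represented by 1 array, read as RMA log2 signals over 70523 probe sets. With 1 array per group there was no spread between replicates, so no p-value was computed and every difference below is described by its size between these 2 arrays. The 22465 genes with a probe set of their own included 15702 above an expression floor of 3.21 log2 units, and the 2 arrays correlated across those genes with a Pearson's r of 0.992, where genes are not independent replicates. The SD of the differences over all genes above the floor was 0.19 log2 units. In 364 olfactory receptor genes, taken as a class that this line should not express, it was 0.17. Other probe sets varied more: the 1343 numbered probe sets without a gene name here, whose type is not given in the sources used here, had an SD of 0.46 log2 units, with 34 at least 2-fold higher and 22 at least 2-fold lower on the array labelled knockdown. Of 8 bacterial and phage control sequences on the array, 7 were lower on that array, with a median difference of -0.18 and the lowest, bioB, at -0.61.

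SREBF1, the target of the hairpin, was not lower on the array labelled SREBP1 knockdown. Its transcript cluster (TC17001192.hg.1) read 5.13 log2 units on the control array and 5.29 on the array labelled knockdown, a difference of 0.15 or 1.11-fold higher. Genes of the same signal level had an SD of differences of 0.20, and SREBF1 lay at their 85.6th percentile. The difference was thus smaller than that SD, and no loss of the target RNA was measured. The directions that follow refer to the label of the array and not to a measured loss of SREBF1. SREBF2, which encodes the related regulator of cholesterol synthesis, read 5.98 on the control array and 6.08 on the array labelled knockdown.

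Genes of fatty acid synthesis and desaturation, the textbook targets of SREBP1, were not lower as a group on the array labelled knockdown. None of the 22 members above the floor differed by 1.5-fold in either direction, 11 were higher and 11 were lower, and their median difference was -0.00029 log2 units, with a mean of the opposite sign, 0.013, and 0.0044 over the 19 members of no other list. It was -0.012 with the median difference of all genes subtracted and -0.030 after a signal-dependent curve was subtracted, both inside the range of random lists. FASN, the fatty acid synthase, was 1.14-fold higher and SCD, the stearoyl-CoA desaturase, was 1.13-fold higher. ACACA and ACLY, which supply malonyl-CoA and cytosolic acetyl-CoA, differed by 0.0044 and 0.0061 log2 units and the desaturase FADS2 by 0.024, differences so small that all 3 turned sign after a signal-dependent curve was subtracted. ELOVL6, a fatty acid elongase, had the lowest value of the list at -0.31 log2 units, or 1.24-fold lower, and lay at the 6.62th percentile of genes of its level. The list's median lay at the 17.6th percentile of 10000 random lists matched on expression, whose central 95% ran from -0.048 to 0.11. In simulations on the same 15702 genes with independent noise, lists of 22 genes shifted by -0.2 log2 units lay below their random range in 100 of 100 trials and lists shifted by -0.1 in 69, while 8 of 100 lists with no shift lay outside it. All trials shared a single draw of the noise. Their lists were picked from all genes, not at this list's signal levels, and every member was shifted equally. The counts are thus only a rough guide to what this list could show. FADS1 was not analysed here, as its probe set named several genes.

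Cholesterol synthesis genes likewise had no member beyond 1.5-fold among 19 measured. Of these, 12 were higher and 6 lower, with a median of 0.028 log2 units, at the 52.8th percentile of the random lists. With the floor 1 log2 unit higher the median was 0.10, at the 93.4th percentile and still inside the range. HMGCS1, which makes HMG-CoA, had the lowest value at -0.41 log2 units, or 1.32-fold lower. SQLE, the squalene epoxidase, was 1.10-fold higher. In the list for sterol uptake and SREBP regulation, 2 of 14 members were lower by at least 1.5-fold and the median was -0.014, or 0.034 over the 12 members of no other list. After a signal-dependent curve was subtracted it was -0.051, and the mean was -0.054, both inside the range of random lists. The 2 lower members were INSIG2, which holds SREBP precursors in the endoplasmic reticulum, at 1.67-fold lower, and the lipoprotein receptor LRP1 at 1.55-fold lower. INSIG1, the paralogue of INSIG2 and a textbook SREBP target, was 1.06-fold higher.

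Other lipid lists also stayed inside the range of random lists. The medians were -0.037 log2 units for triglyceride and phospholipid synthesis, 0.020 for lipid droplets and lipolysis (below 0 after a signal-dependent curve was subtracted), -0.0049 for fatty acid oxidation and 0 for LXR targets and sterol efflux. LPCAT2, a lysophosphatidylcholine acyltransferase, was the 1 of 29 glycerolipid genes beyond 1.5-fold and was 1.70-fold lower. CPT1A, which commits fatty acids to mitochondrial oxidation, was the 1 of 26 oxidation genes beyond 1.5-fold and was 1.54-fold higher. No member of the lipid droplet list (22 genes) or of the LXR list (15 genes) differed by 1.5-fold.

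Across all genes above the floor, 3 were at least 2-fold higher and 18 at least 2-fold lower on the array labelled knockdown, and all of them encode proteins. At 1.5-fold the counts were 60 higher and 118 lower. PDE7B, a cyclic AMP phosphodiesterase, was lowest, at 6.06 log2 units on the control array and 4.13 on the other, or 3.79-fold lower. EDIL3, a secreted integrin ligand, was 3.10-fold lower, and the interferon-inducible GTPase GBP2 was 2.82-fold lower. FN1, which encodes fibronectin, was 2.40-fold lower, from 7.32 to 6.06 log2 units. The TNF family ligands TNFSF15 and TNFSF10 (TRAIL) were 2.32-fold and 2.31-fold lower. PTGES, a prostaglandin E synthase, was 2.32-fold lower, KLHL4 2.31-fold, the hyaluronan-binding protein CEMIP 2.25-fold, the splicing regulator MBNL2 2.20-fold and the mesenchymal cadherin CDH11 2.16-fold. CCL2, a monocyte chemokine, read 4.46 log2 units on the control array and 3.11 on the other, which is under the floor, so that it was lower by at least 1.25 log2 units. BMP4, a secreted ligand, was 2.08-fold lower. The remaining genes of this set, named after their values were seen, were PARD6B, DAAM1, MAP3K1 and C3, between -1.08 log2 units for PARD6B and -1.02 for C3, and SLC2A12. SLC2A12 was under the floor on the array labelled knockdown and was lower by at least 0.996 log2 units, just under 2-fold, so that 17 genes were at least 2-fold lower with values under the floor set to it, an alternative chosen after seeing the data.

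The highest gene on the array labelled knockdown was SLC7A11, the cystine transporter, at 7.42 log2 units on the control array and 8.59 on the other, or 2.25-fold higher. KISS1, a gene known as a metastasis suppressor, was 2.15-fold higher and MARCHF4, a membrane ubiquitin ligase, 2.01-fold higher. MARCHF4 was under 2-fold once the median difference of all genes, 0.012 log2 units, was subtracted. The imprinted gene MEST was 1.93-fold higher, TMEM170A 1.83-fold, the xenobiotic-inducible cytochrome CYP1A1 1.77-fold and the interleukin receptor IL7R 1.75-fold. AGMAT was 1.74-fold higher, the lipoprotein lipase inhibitor ANGPTL4 1.73-fold, the proteoglycan SRGN 1.69-fold, STOM 1.64-fold and ODC1, the first enzyme of polyamine synthesis, 1.62-fold. In the simulations, genes set 2-fold apart passed the 2-fold threshold in 56% of cases, those set 3-fold apart in 100% and those set 1.5-fold apart in 0%, while 0 of 15502 unchanged genes passed. The simulated noise was normal, with an SD from the differences between these 2 arrays, so 2-fold lay far out in its tails. The 0 of 15502 was thus largely fixed by the setting and gives no rate of false calls. The noise was also independent between genes and holds no spread between replicates.

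**Figure D1:**
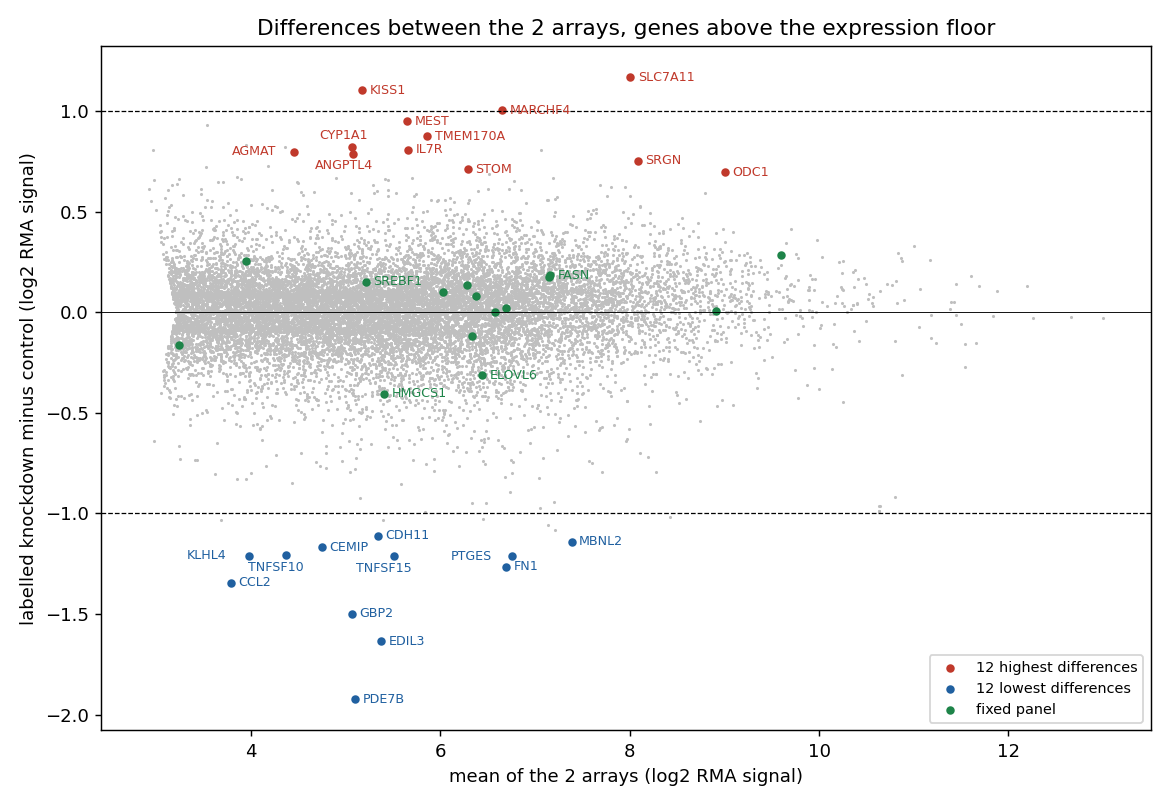
Difference between the arrays (labelled knockdown minus control, log2 RMA signal) against the mean of the 2 arrays for each of the 15702 genes above the floor (grey points). The 12 highest and 12 lowest protein-coding genes and the fixed panel are coloured, dashed lines mark 2-fold, and SREBF1 lies at 0.15.

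Targets of the hypoxia factor HIF1 were lower as a group on the array labelled knockdown, with the lowest median of the 34 lists. Of 30 members above the floor, 27 were lower and 2 higher, 8 were lower by at least 1.5-fold, and the median difference was -0.35 log2 units. LOX, which crosslinks collagen, was 1.81-fold lower, INSIG2 1.67-fold, PDK1, which inhibits pyruvate dehydrogenase, 1.61-fold, the carbonic anhydrase CA12 1.59-fold and PFKFB4, a regulator of glycolysis, 1.55-fold. The other 3, named after their values were seen, were the mitophagy receptors BNIP3 at -0.63 and BNIP3L at -0.59 log2 units and the stress gene NDRG1 at -0.59. ANGPTL4 went the other way. None of the 10000 random lists had a median this low, and their central 95% ran from -0.041 to 0.093. Random lists break up co-regulated genes, so these percentiles describe the 2 arrays and are not tests of the conditions.

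Glycolysis genes were also lower, 18 of 22 members, with a median of -0.12 log2 units at the 0.01th percentile of the random lists. The members beyond 1.5-fold were PDK1 and PFKFB4, which are also in the hypoxia list. In the 15 glycolysis members found in no other list the median was -0.058, at the 3.23th percentile, inside the central 95%. For hypoxia, the 16 members found in no other list had a median of -0.36, below every random list. Subunits of oxidative phosphorylation had a median of -0.013 over 30 genes, none beyond 1.5-fold, and of -0.060 after the signal-dependent curve was subtracted, inside the random range at the 4.67th percentile.

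Genes of the TGF-beta pathway had 20 of 29 members lower and a median of -0.089 log2 units, at the 0.155th percentile. The members beyond 1.5-fold were BMP4, given above, and FST, which binds activin, at 1.56-fold lower. Matrix proteases and their inhibitors had a median of -0.095 over 27 genes, at the 0.08th percentile, with 14 members lower and 11 higher. The member beyond 1.5-fold was the protease inhibitor TIMP3, 1.74-fold lower. By its mean, -0.058, the protease list lay at the 2.59th percentile, inside the central 95%, and with no floor its median was -0.044, below it. In the mesenchymal list 4 of 28 members were lower by at least 1.5-fold and none higher. FN1, CDH11 and LOX are given above, and the fourth, the matrix protein TNC, named after its value was seen, had a difference of -0.67 log2 units. The list's median of -0.032 lay inside the range of random lists, at the 5.1th percentile, whereas its mean of -0.16 lay below all of them. The median also lay below the range after the signal-dependent curve was subtracted (-0.068), with probe sets averaged (-0.049), with the raised floor (-0.084) and over the 17 members of no other list (-0.094). VIM, the mesenchymal filament protein vimentin, was 1.22-fold higher, the transcription factor SNAI1 was higher by 0.26 log2 units and ZEB1 was 1.09-fold lower. The epithelial list had a median of -0.0053 over 26 genes, and JUP (plakoglobin), the 1 member beyond 1.5-fold, was 1.55-fold lower. The mean of the epithelial list was -0.068, below the random range at the 2.15th percentile. CDH1, which encodes E-cadherin, read 3.32 log2 units on the control array and 3.16 on the other, close to or under the floor. Integrins and focal adhesion genes had a median of -0.021 over 27 genes, with ITGA2, a collagen receptor subunit, 1.68-fold lower. That median lay inside the random range, but the mean of -0.063 and the median of -0.082 after the curve was subtracted lay below it, at the 1.29th and 1.9th percentiles, and the 23 members of no other list had a median of 0.0038.

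Cytosolic ribosomal protein genes were slightly higher, 30 of 31 members, with a median of 0.12 log2 units at the 99.0th percentile of the random lists and none beyond 1.5-fold. The median was 0.067 after a signal-dependent curve was subtracted, still above its random range. Replication-dependent histones were higher in 14 of 16 measured members, with a median of 0.16 at the 99.8th percentile and none beyond 1.5-fold, while 29 of the 52 members shared probe sets with other genes. With the floor 1 log2 unit higher, 13 histone genes were above it and the list lay inside the random range, at the 97.4th percentile. The cell cycle list had a median of 0.083 over 46 genes, inside the random range, with CCNE1 (cyclin E1) 1.59-fold higher. It lay above random lists not matched on expression, at the 99.0th percentile, and its median was 0.029 after the curve was subtracted. The list of p53 targets and cell death had a median of 0.070 over 24 genes and no member beyond 1.5-fold.

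Among stress lists, targets of ATF4 and amino acid metabolism had 24 of 34 members higher and a median of 0.082, at the 95.8th percentile and inside the central 95%. The list lay above that range by its mean (0.10, 99.6th percentile), with the raised floor (0.12, 99.7th), after the curve was subtracted (0.062, 97.9th) and against unmatched random lists (97.7th). SLC7A11 and the amino acid transporter SLC7A5, at 2.25-fold and 1.51-fold, were the members beyond 1.5-fold upward, and DDIT4, an inhibitor of mTORC1, was 1.76-fold lower. The NRF2 and ferroptosis list had a median of 0.014 over 28 genes, 14 higher and 14 lower, with SLC7A11 and OSGIN1 (1.51-fold) higher. Its mean was 0.093, above the random range at the 97.6th percentile, and its median was 0.069 with the raised floor and -0.030 after the curve was subtracted, both inside. The unfolded protein response list, over 26 genes, and the autophagy and lysosome list, over 34, had medians of 0.036 and -0.023 and no member beyond 1.5-fold. Interferon-stimulated genes went both ways, with a median of 0 over 31 genes, 1 higher and 3 lower by at least 1.5-fold, and a median of 0.037 over 38 genes with no floor, inside the random range. SAMD9L was 1.74-fold lower, BST2 1.60-fold lower and HERC5 1.51-fold higher, and GBP1, named after its value was seen, had a difference of -0.63 log2 units. NF-kB targets and cytokines had a median of 0.077 over 27 genes but a mean of -0.010, with CCL2 and TNFAIP2 (1.53-fold) lower and IL24 1.61-fold higher. YAP and TEAD targets had a median of 0.0079 over 27 genes, which turned sign when the median of all genes or the curve was subtracted and over the 20 members of no other list, with RBMS3 1.54-fold lower and FJX1 1.53-fold higher. It was 0.049 with probe sets averaged, and the mean was 0.060, both inside the random range. Medians were -0.010 for growth factor receptors and ligands, 0.024 for breast stem cell markers and -0.014 for immediate early genes, and no member of these 3 lists was beyond 1.5-fold. The immediate early list had a mean of the opposite sign, 0.012. After the curve was subtracted, the medians were -0.0097 for the unfolded protein response, -0.0026 for stem cell markers and -0.058 for growth factor receptors, all inside their random ranges, as were the mean of -0.042 for growth factor receptors and the median of 0.067 for stem cell markers with the raised floor.

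Markers of other cell types were examined as a check of the cells on each array. Luminal and oestrogen receptor markers had a median of -0.12 log2 units over 13 genes, at the 0.51th percentile, and CA12, which is also in the hypoxia list, was the member beyond 1.5-fold. Leukocyte markers had a median of 0.11 over 17 genes, at the 99.0th percentile, with no member beyond 1.5-fold. Both lists came inside the random range when no floor was applied, with medians of 0. The luminal list was also inside it over the 7 members of no other list, at the 2.8th percentile, and the leukocyte list with the raised floor, with the floor on the mean of the arrays and by its mean. Fibroblast and endothelial markers had medians of -0.012 over 10 genes and 0.087 over 12 genes, and the genes of liver and muscle, which this line should lack, had a median of 0.048 over 18 genes, all inside the range. The endothelial list lay above it by its mean (0.13, 99.2th percentile) and with the raised floor (0.16 over 7 genes, 98.6th) and had a median of 0.029 with no floor, the fibroblast median was 0.081 over the 5 members of no other list, and the liver and muscle median was 0 with no floor and with the raised floor. Of the 34 lists, 5 lay below and 3 above the central 95% of their random lists. If the genes of a list varied independently, 1.7 would be expected outside. Co-regulated genes do not, and the lists share members, so the excess has no test. Even with independent noise, 7 of 100 unshifted simulated lists of 30 genes and 8 of 100 of 22 genes lay outside.

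**Figure D2:**
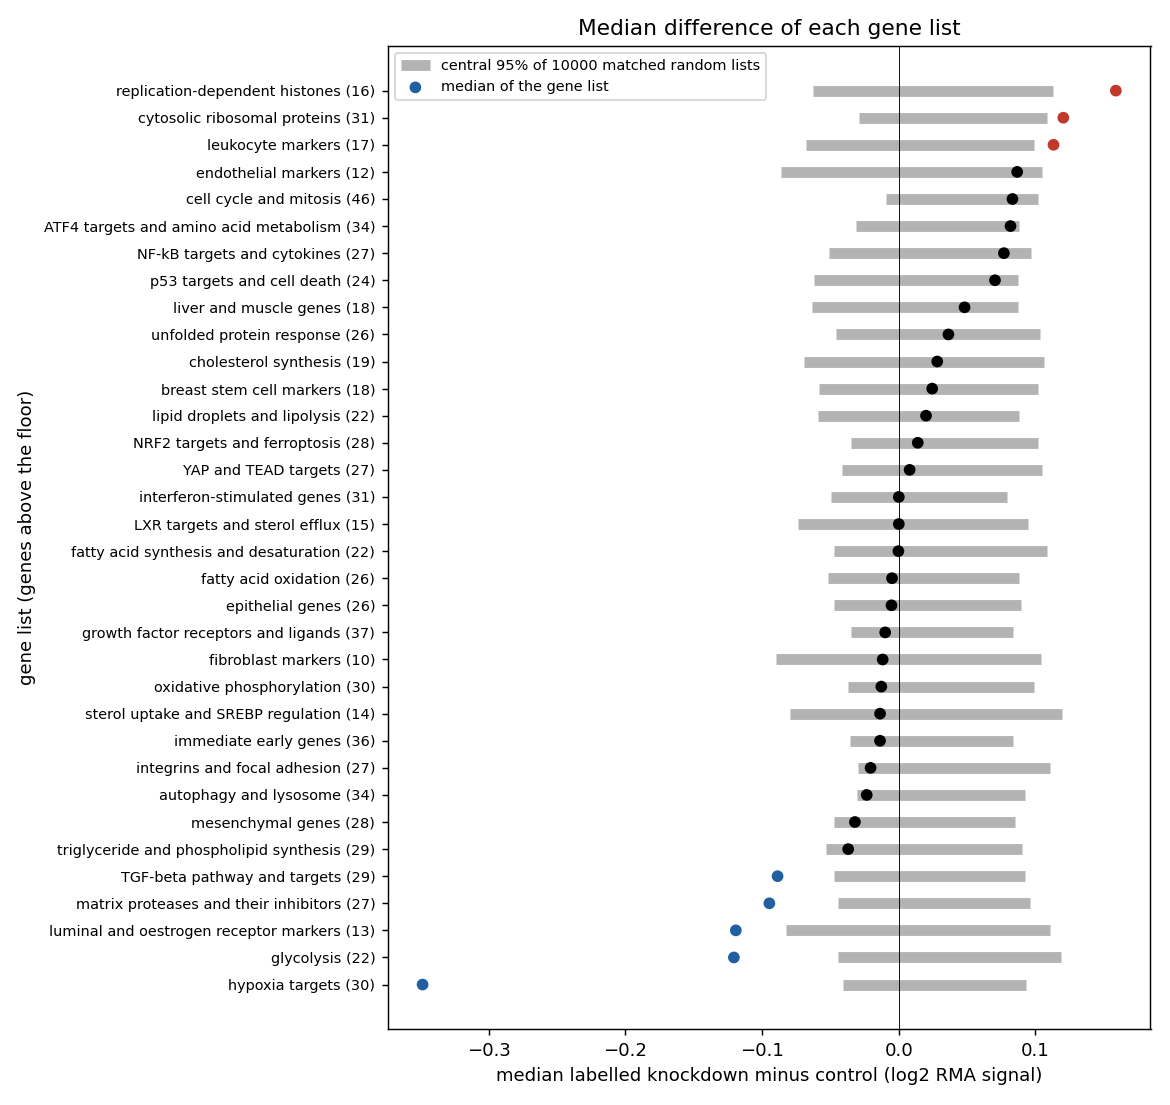
Median difference (labelled knockdown minus control, log2 RMA signal) of each of the 34 gene lists (points, with the number of genes above the floor) against the central 95% of 10000 expression-matched random lists (grey bars). Hypoxia targets lie at -0.35, far below their bar, and fatty acid and cholesterol synthesis lie inside theirs.

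**Figure D3:**
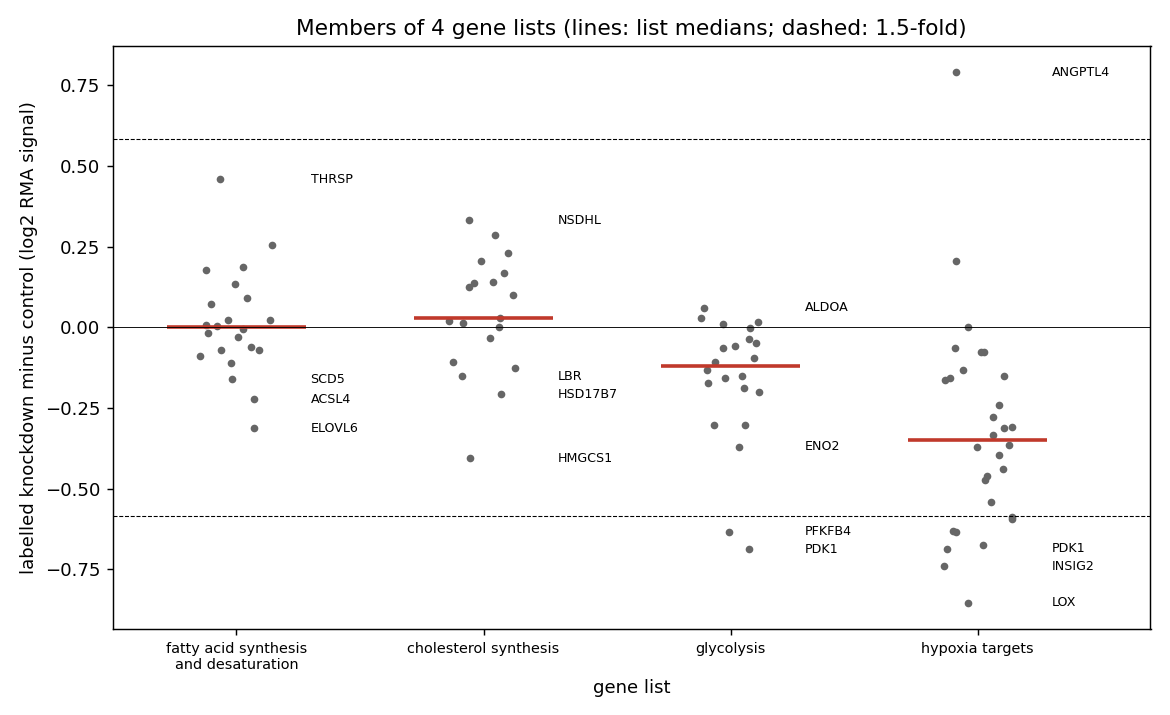
Difference between the arrays (labelled knockdown minus control, log2 RMA signal) of each member above the floor (points) of 4 gene lists, with list medians (red lines) and 1.5-fold in either direction (dashed). No fatty acid or cholesterol synthesis gene crosses a dashed line, and 8 hypoxia targets lie below the lower one.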

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

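Transcript clusters without a gene name in the annotation used, which no comparison above includes, held 17 distinct values at least 2-fold higher and 35 at least 2-fold lower on the array labelled knockdown, out of 14965 distinct values above the floor. They were singled out by a count of the 17 higher values, in data no comparison reported on, although more values were lower. The highest was TC15001877.hg.1, at 2.92 log2 units on the control array and 4.51 on the other, and the lowest was TC22001201.hg.1, at 5.05 and 2.83, and the smaller value of each was under the floor, so these sizes are uncertain. The SD of the differences in these clusters was 0.23 log2 units.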

How the results depend on the processing

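No paired analysis was possible because each group had 1 array, and leaving out a replicate was not possible either. SREBF1 was higher on the array labelled knockdown under all 3 alternatives run for it (median difference subtracted, loess curve subtracted, probe sets averaged), and in 186 recomputed values of the other named genes under these none moved by more than the SD of genes at its level. Each of these genes had 1 probe set, so averaging could not change its value. The median subtracted was 0.012 log2 units for every gene, so only the loess curve could have moved a value by that SD. The count of genes at least 2-fold lower ranged from 17 to 24 and the count higher from 2 to 4 over the scaling, floor, probe and gene-type alternatives, with 17 lower and 3 higher when values under the floor were set to it (chosen after seeing the data). At 1.5-fold the counts were 118 lower and 60 higher, and at 3-fold 2 lower (PDE7B and EDIL3) and 0 higher, with no test in any case. The hypoxia median was -0.39 after loess and lay below every random list under all alternatives. Glycolysis had a median of -0.17 after loess, a mean of -0.16 and a median of -0.058 in members of no other list (an alternative chosen after seeing the data), the last inside the random range. Matrix proteases gave -0.13 after loess, -0.044 with no floor and a mean of -0.058, the mean inside the range. TGF-beta genes had a mean of -0.13. Ribosomal proteins were at 0.067 after loess, above the range. Cholesterol synthesis was 0.10 with the floor 1 log2 unit higher, inside its range. Luminal markers were 0 with no floor, and in the 7 members of no other list -0.11, at the 2.8th percentile, both inside. Leukocyte markers were 0 with no floor, 0.012 with the raised floor and had a mean of 0.031, all inside, as was the 89.3th percentile with the floor on the mean. Histones reached the 97.4th percentile with the raised floor, just inside. Lists inside the range in the main setting left it under some alternatives: mesenchymal genes in 5, ATF4 targets in 4, integrins and endothelial markers in 2 each, and cell cycle, epithelial and NRF2 lists in 1 each. The cause of these moves was not tested, except that the floor alternatives change which genes are in a list. Signal over background limits genes near the floor, such as CDH1.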

Other observations

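All tests of explanations in this part, and the RNAs named in this paragraph, were chosen after the results were seen. Small nucleolar RNAs had a wider spread of differences between the arrays than the protein-coding, long non-coding and microRNA classes. Among 120 snoRNA genes above the floor, the SD of the differences was 0.34 log2 units, against 0.19 for 13125 protein-coding genes, with 7 distinct values higher and 8 lower by at least 1.5-fold. The 5 U3 snoRNA genes, which take part in processing of ribosomal RNA, were all lower on the array labelled knockdown, from -0.99 for SNORD3B-1 and SNORD3B-2 to -0.92 for SNORD3A. SNORD3B-1 and SNORD3B-2 had identical values, and as near-identical copies the U3 genes are uncertain as separate measurements. SNORA14A and SNORD93 were higher by 0.82 and 0.81 log2 units. Long non-coding RNAs (793 genes) had a median difference of 0 and an SD of 0.18, and 407 microRNA genes a median of 0.036 and an SD of 0.22.

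The absence of a lower SREBF1 signal on the array labelled knockdown is the first pattern a reader may wish to follow up. The lower of the SREBF1 values lay 1.93 log2 units above the floor, which argues against a signal at the level of olfactory receptor genes. Background control probe sets of the array, named by GC number, reached higher signals. Those named GC19 and GC20 read 5.05 and 5.44 log2 units on the control array, where SREBF1 read 5.13. On the other array they read 4.96 and 5.35, where SREBF1 read 5.29. The GC content of the SREBF1 probes is not given here, so a signal at background stays open. A swap of the arrays would predict fatty acid synthesis genes above random lists on the array labelled knockdown, and a loss of SREBP1 activity without a loss of its RNA would predict fatty acid and cholesterol genes below them. The fatty acid list lay at the 17.6th percentile and the cholesterol list at the 52.8th, inside the range, so neither predicted outcome was seen. Cholesterol genes are textbook targets of the regulator encoded by SREBF2 and only in part of SREBP1, so their place weighs little on SREBP1 activity. In the simulations above, lists of 22 genes shifted by 0.2 log2 units left their range upward in 99 of 100 trials. Those shifted by -0.2 left it downward in 100. For shifts of 0.1 and -0.1 the counts were 64 and 69, so smaller shifts could be missed. The 2 explanations thus cannot be told apart with these data, and neither is excluded. A hairpin without effect in the cells hybridised stays open too.

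The second pattern is the lower signal of hypoxia targets. A trend with signal level between the arrays is argued against, since the list's median was -0.39 log2 units after a loess curve was subtracted, below every random list. An effect of the hairpin and the culture conditions behind the 2 arrays, such as density or time since feeding, cannot be told apart, because the design has 1 array per group. SREBF1 itself was not lower on the array labelled knockdown. As a hypothesis, the hypoxia and glycolysis differences may come from culture conditions that affect oxygen supply, and replicate cultures would be needed to test it.

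The third pattern is that more genes were 2-fold lower (18) than 2-fold higher (3) on the array labelled knockdown. A trend with signal level is argued against, since 24 genes were lower and 2 higher after the loess curve was subtracted. Of the 18 lower genes, 16 were above the floor on both arrays. For these, noise at the level of olfactory receptor genes is argued against. Background control probe sets reached higher signals, with GC19 at 4.96 log2 units on the array labelled knockdown. Some of the 16 read less there, such as KLHL4 at 3.37, and some more, such as FN1 at 6.06. The GC content of their probes is not given here, so noise at background stays open. Variation between single arrays stays open, since numbered probe sets without a gene name here, whose type is not given, also reached 2-fold: 15 were lower and 27 higher among those above the floor on at least 1 array, and 9 were lower and 11 higher among those above it on both. Some controls of known type leaned lower in their medians. The median difference of all genes above the floor was 0.012 log2 units, so the genes leaned lower only in the counts of large differences. Of 8 bacterial and phage control sequences 7 were lower and 1 higher, with a median of -0.18 log2 units. The 32 AFFX control probe sets, which include these 8 and are mostly background probe sets named by GC number, had a median of -0.074, with 0 beyond 2-fold. The 155 probe sets for ERCC control sequences had a median of 0. With 1 array per group, variation between single arrays, differences between single cultures and an excess of lower genes in the cells labelled knockdown cannot be told apart.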
